A study of Homo sapiens with 4 samples.

How the data were processed

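The series holds 4 groups of A375 human melanoma cells, a BRAF-mutated line, with 1 library in each. A line resistant to the BRAF inhibitor encorafenib and the sensitive line were each left untreated or given 10 nM encorafenib for 48 h, per the labels. Per the labels' protocols, total RNA was prepared with RNeasy Mini kits and libraries were made with the SMARTer smRNA-Seq kit and sequenced on an Illumina NextSeq instrument. Each library has a table of raw read counts per gene and a table of raw read counts per mature microRNA, both deposited by the authors without normalization, per the file headers. The genome build was hg19, per the submitters' processing notes. The aligner, the counting program and its treatment of reads with several matches are not given in the sources used here.

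The gene table has 46416 entries with a symbol, an Entrez identifier and a biotype, of which 19659 are protein-coding and 8865 reached 10 counts in at least 1 library. The microRNA table has 644 entries, of which 190 reached 10 counts. Of the 8865 entries, 542 had counts identical to another entry in all 4 libraries, among them 369 protein-coding, 112 tRNA and 21 rRNA entries. Genes with near-identical copies are therefore reported as uncertain. So are protein-coding genes with an exon that overlaps a small RNA gene, which 290 of the 7916 protein-coding genes tested had. Overlap, GC content, transcript length and gene order came from the GRCh38 annotation matched by name and identifier, with no coordinates carried over; 99.7% of the protein-coding genes tested had values.

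Gene-table totals ran from 20507667 to 33664470 counts per library. Most of these counts were rRNA, and protein-coding genes took 326919 counts in untreated resistant cells, 307026 in treated resistant cells, 435351 in untreated sensitive cells and 215894 in treated sensitive cells. A floor of 3 counts, the limit that a count of 0 allows, stands at 9.18, 9.77, 6.89 and 13.9 CPM of protein-coding counts in these libraries. MicroRNA-table totals were 20808, 59045, 7041 and 4395 counts in the same order.

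Libraries were scaled with TMM factors (edgeR 4.0.16, R 4.3.3). For each of 4 pairs of libraries, the log2 ratio of scaled counts was computed with a prior count of 0.5, with an exact conditional (Clopper-Pearson) 95% interval (scipy 1.17.1). A gene was counted as beyond 2-fold where the bound nearest 0 was at least 1 in log2. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. A ratio between 2 libraries compares those libraries, not the conditions; no pairwise difference has a replicate check and none is given a p-value. Where a library had 0 counts, a single gene is given with the bound nearest 0 of its 95% interval, in log2. In lists, a member at 0 placed at its bound takes its ratio against 3 counts in that library, which is not a 95% bound.

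An additive fit of line and drug to all 4 libraries used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, on genes with at least 10 counts in at least 2 libraries. It has 1 residual degree of freedom, which is the difference of responses between the lines, and the libraries of a line are not labelled as replicates. Its p-values are therefore set against the difference of responses between the lines. Spread between libraries of 1 condition was not observed, since each group has 1 library. The common biological coefficient of variation was 23.7%. The difference of the 2 drug responses has no residual at all and is given with a delta-method counting interval.

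Before the data were examined, 26 gene lists and 6 microRNA lists were fixed, and the choice of named genes with them. For each list with at least 3 detected members, the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Its 95% interval comes from 2000 Poisson redraws of the members' counts. A count of 0 is redrawn as 0, so members at 0 add no error and the interval can be too narrow. For MAPK outputs between lines under drug, the median with members at 0 at their bound, 0.41, lay outside 0.49 to 1.62. The interval from redraws replaced one from summed counts, because abundant members decide a sum. The replacement came after the first comparison of settings had been seen, and it also made fewer values count as moved. Named genes are the 10 higher and 10 lower protein-coding genes of each gene comparison with at least 50 counts in the higher library and the largest bound nearest 0, the same for both line comparisons together, and 5 and 5 for microRNA. Up to 4 members of a list were named by the same bound, a ranking chosen after the data were seen. NCOA4, FTH1, FTL, TFRC, SLC40A1, BRAF and MITF were always reported. Some genes that these rules name are not reported here. Genes drawn in plots and genes named for a difference of responses were chosen after their values were seen.

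The pairwise step was tested on simulated counts for the real genes. For untreated resistant against untreated sensitive cells it recovered 2, 46, 96 and 98% of 50 genes changed 2-, 4-, 8- and 16-fold among 8865, and called 0 unchanged genes. Between lines under drug and with drug in sensitive and resistant cells it recovered 38, 34 and 48% at 4-fold and 84, 84 and 90% at 8-fold, and called 7, 5 and 3 unchanged genes. The counting intervals held the true ratio for 96.5 to 96.9% of genes, so the simulated counts varied little beyond counting error. The numbers of unchanged genes called therefore do not cover spread between cultures or libraries. In the additive line effect, 8, 74, 98 and 100% of 50 genes at those sizes were recovered among 7092, with 4 unchanged genes called. Of 200 simulated unchanged lists of 15 genes, 10 lay outside the 95% range.

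The alternatives tried were DESeq2 size factors (DESeq2 1.42.0), total counts, other count minimums, thinning to the smallest library, protein-coding genes only, 2-fold at the point estimate, a prior count of 3, means in place of medians, 5 expression bins, DESeq2's Wald test, limma-voom (limma 3.58.1), 1 factor only and each library left out. Chosen after the data were seen were entries with identical counts taken once, removal of genes that overlap a small RNA gene, the additive fit on protein-coding genes, and 3 alternatives for the difference of responses.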

Results

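Gene and microRNA read counts were compared in A375 melanoma cells, a BRAF-mutated line, that were either sensitive or resistant to encorafenib, an inhibitor of mutant BRAF. Each line was sequenced untreated and after 48 h in 10 nM encorafenib, with 1 library per group. The series addresses how resistance changes transcription, with iron trafficking through NCOA4, the receptor that delivers ferritin to autophagy, as its stated subject. Gene-table totals were 23029101 counts in untreated resistant, 20507667 in treated resistant, 33664470 in untreated sensitive and 25539835 in treated sensitive cells. Values below are log2 ratios with 95% counting intervals in parentheses unless a fold is named.

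The libraries held mostly structural RNA, and short RNA classes differed between the lines. Ribosomal RNA took 92.4%, 88.7%, 93.8% and 93.8% of the counts in the order above, and snoRNA 4.74%, 7.38%, 3.46% and 3.95%. Protein-coding genes took 1.42% (1.41 to 1.42, Clopper-Pearson), 1.497% (1.49 to 1.502), 1.29% (1.29 to 1.30) and 0.845% (0.842 to 0.849). tRNA counts per gene-table read were 6.22-fold higher in resistant than in sensitive cells without drug and 11.5-fold higher with drug. MicroRNA-table reads per gene-table read were 4.32-fold higher (4.20 to 4.44) without drug and 16.7-fold higher (16.2 to 17.3) with drug. Scaling by total counts in place of TMM moved the median gene by 0.78 in the line ratio under drug, by -0.57 in the drug ratio of sensitive cells, by 0.12 in that of resistant cells and by 0.10 in the untreated line ratio, so changes are reported relative to TMM scaling.

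Untreated resistant cells had more TIMP1, TFRC and FTH1 transcript than untreated sensitive cells and less transcript of proliferation genes. TIMP1, an inhibitor of matrix metalloproteinases, was 7.22-fold higher, with a log2 ratio of 2.85 (2.69 to 3.02). TFRC, the transferrin receptor that imports iron, was 10.3-fold higher (5.12 to 23.5), and FTH1, the ferritin heavy chain that stores it, 5.27-fold higher (4.43 to 6.31). TBC1D4, a regulator of vesicle traffic, had a log2 ratio of -2.91 (-3.60 to -2.32), and ASPM, a mitotic spindle protein, one of -2.12 (-2.77 to -1.56). Of 8865 genes, 255 were higher and 102 lower beyond 2-fold at the bound, among them 80 and 64 protein-coding genes. The higher set held 90 tRNA and 57 snoRNA genes, beside the larger yield of short RNA in that library.

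The other higher genes named by size were TFPI2, a serine protease inhibitor, at 3.49 (2.65 to 4.61), the secreted hormone STC1 at 2.82 (2.17 to 3.60), the complement regulator CD55 at 2.36 (2.17 to 2.56), the ATP synthase subunit ATP5F1E at 2.40 (2.10 to 2.71), the DNA polymerase epsilon subunit POLE4 at 2.90 (2.03 to 4.04), the interferon-induced IFI6 at 2.87 (1.91 to 4.16) and the integrin activator FERMT1 at 2.47 (1.87 to 3.18). Lower genes included the BMP antagonist CHRDL1 at -3.44 (-5.94 to -1.98), with 3 counts against 50, the neuropeptide precursor VGF at -2.04 (-2.43 to -1.68) and the kinase HIPK2 at -1.75 (-2.06 to -1.46). The remaining lower genes encode histones, whose near-identical copies make single genes uncertain. H3C15 had 0 counts against 190, at least 46.5-fold lower, while its copy H3C14 had 39 against 37. H3C3 stood at -2.58 (-3.63 to -1.76), H2BC21 at -2.36 (-3.24 to -1.63), H2AC14 at -2.72 (-4.31 to -1.59) and H2AC20 at -1.87 (-2.36 to -1.42).

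By list, 20 detected proliferation genes had a median of -1.44 (-1.76 to -1.05), at percentile 0 of the matched random lists, and 12 of them had an interval below 0. TOP2A stood at -1.55 (-1.97 to -1.16) and MKI67 at -1.63 (-2.22 to -1.10). The 8 replication histones had a median of -1.06 (-1.53 to -0.81), at percentile 0.01. Interferon-response genes had a median of 1.21 (0.83 to 1.84) over 20 members, at percentile 100, led by ISG15 at 4.34 (2.35 to 10.33), with 23 counts against 1. Beside this, the immune marker LYZ had 13 counts against 1, at 3.54 (1.41 to 9.56), and the immune marker CD68 22 against 6, at 2.22 (0.97 to 3.91). Hypoxia and glycolysis genes had a median of 1.01 (0.68 to 1.24) over 14 members, at percentile 100, with ALDOA at 1.70 (1.31 to 2.11) and NDRG1 at 1.78 (1.16 to 2.47). Cell-matrix genes had a median of 0.49 (0.28 to 0.87) at percentile 99.6, with 5 of 16 members beyond 2-fold, among them ITGA2 at 1.97 (1.49 to 2.51) and TIMP3 at 1.66 (1.42 to 1.91). Autophagy and lysosome genes had a median of 0.44 (0.21 to 0.68) at percentile 99.6, with SQSTM1 at 1.21 (0.98 to 1.46), and mitochondrial respiration genes one of 0.50 (0.21 to 0.65) at percentile 99.4. Housekeeping genes stood as high as the last 3 lists, at 0.52 (0.12 to 0.74) and percentile 97.8. The p53 target list had a median of 0.48 (0.24 to 0.91) at percentile 97.7, with CDKN1A at 1.76 (1.35 to 2.21). Transcriptional outputs of the MAPK pathway had a median of -0.15 (-0.35 to 0.14) over 16 members, at percentile 14.0, with a mean of 0.03.

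Under encorafenib, resistant cells exceeded sensitive cells in interferon genes and in single genes such as SLC7A5 and FTH1. SLC7A5, an amino acid transporter, had 100 counts against 6, a log2 ratio of 3.48 (2.39 to 5.05). S100A6, a calcium-binding protein, stood at 2.60 (2.28 to 2.94), TIMP1 at 2.57 (2.18 to 3.00) and FTH1 at 1.88 (1.69 to 2.07). The pigment enzyme DCT was lower in resistant cells at -1.68 (-1.98 to -1.40), as was the melanosome glycoprotein GPNMB at -1.49 (-1.92 to -1.08). Of 8865 genes, 240 were higher and 110 lower, 54 and 39 of them protein-coding and 117 of the higher ones tRNA, beside the 11.5-fold larger tRNA yield. Under scaling by total counts the same counts were 716 higher and 31 lower.

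Further higher genes were NIBAN2 at 3.16 (1.85 to 5.21), FTCDNL1 at 2.26 (1.77 to 2.81), the glycogen phosphorylase PYGB at 2.69 (1.70 to 4.02), the sulfate transporter SLC26A2 at 1.89 (1.64 to 2.16), the neurofilament gene NEFL at 2.75 (1.62 to 4.33) and the ubiquitin-like ISG15 at 2.67 (1.62 to 4.11). Further lower genes were the transcription factor NFATC2 at -1.55 (-1.89 to -1.24), the collagen receptor ITGA2 at -1.54 (-2.04 to -1.07) and ZNF608 at -1.67 (-2.45 to -0.97), the last short of 2-fold at its bound. DKC1 at -1.95 (-2.15 to -1.76), TMEM107 at -1.83 (-1.96 to -1.70), WDR74 at -1.18 (-1.23 to -1.14) and RANBP1 at -1.34 (-1.63 to -1.06) were also lower but have exons that overlap small RNA genes, so their counts are uncertain. The interferon list again had a high median, 1.40 (1.04 to 1.85) at percentile 100, or 1.01 over members with at least 50 counts, with 6 of 20 members beyond 2-fold, among them IFI44L at 3.74 (1.60 to 9.56) with 26 counts against 1 and IFIT1 at 2.97 (1.47 to 5.47). Hypoxia and glycolysis genes had a median of 0.96 (0.76 to 1.30) at percentile 100, with LDHA at 1.67 (1.16 to 2.22), and p53 targets one of 0.81 (0.45 to 1.42) at percentile 99.9. Outputs of the MAPK pathway had a median of 0.81 (0.49 to 1.62) at percentile 99.97, or 0.41 with members at 0 placed at their bound, with CCND1 at 2.16 (1.07 to 3.62) and EGR1 at 2.47 (0.92 to 4.99). The amino acid and unfolded-protein response list had a median of 0.57 (0.18 to 0.86) at percentile 99.2, led by PHGDH at 2.57 (1.03 to 5.09). Autophagy and lysosome genes had a median of 0.05 (-0.06 to 0.48) under drug, at percentile 46.0, and cell-matrix genes one of 0.12 (-0.04 to 0.49) at percentile 63.2. Proliferation genes, at few counts in both treated libraries, had a median of 0.15 (0.00 to 0.83) at percentile 51.6.

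The pair of line comparisons shares no library, and in both of them 132 genes were higher and 14 lower beyond 2-fold, where independent lists would share 6.90 and 1.27. Of these, 14 and 1 were protein-coding, and 11 genes went opposite ways. The expected numbers take all entries as independent, which they are not. Among tRNA entries 112 had counts identical to another entry, and both resistant libraries had a larger tRNA yield. No expected number was computed for protein-coding genes alone, so the excess is not evidence about them. Higher in both were TIMP1, FTH1, ISG15, S100A6, NEFL, CD55, the cell cycle inhibitor CDKN1A, the stress-induced NDRG1, the glycolytic enzyme PKM and the protease inhibitor SERPINE2. Without and with drug PKM stood at 1.62 (1.35 to 1.91) and 1.49 (1.13 to 1.87), and SERPINE2 at 1.15 (1.05 to 1.25) and 1.65 (1.33 to 1.98). The lower genes with the largest shared bound were DKC1, TMEM107, the growth factor MDK, the histone H4C6, SMARCA1, the p53 regulator MDM4, INPP4B, SOX5, SCAF11 and the fatty acid desaturase SCD. Among these DKC1 alone passed 2-fold at the bound in both comparisons, with overlapping small RNA. MDM4 stood at -1.93 (-2.94 to -1.09) and -1.39 (-2.28 to -0.60), and MDK at -1.78 (-2.91 to -0.87) and -1.88 (-2.85 to -1.06). Across 509 protein-coding genes with at least 50 counts in every library, the line ratios correlated with Pearson's r of 0.518 and Spearman's rho of 0.401, with the same sign in 64.2%; genes are not independent replicates.

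**Figure D1:**
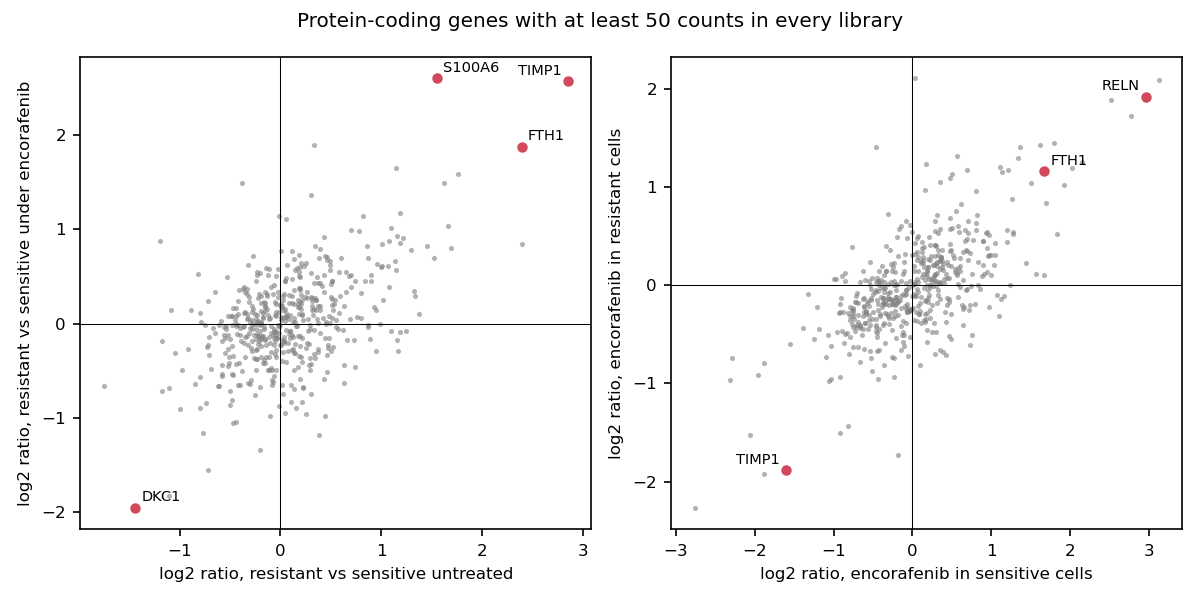
Log2 ratios of 509 protein-coding genes with at least 50 counts in every library, resistant against sensitive cells without (x) and with (y) encorafenib on the left, and encorafenib against untreated in sensitive (x) and resistant (y) cells on the right. Each point is 1 gene; red points are genes chosen after their values were seen, with TIMP1, FTH1 and S100A6 at the upper right of the left panel and RELN at the upper right of the right panel.

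In the additive fit, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 173 of 7092 genes between the lines, 142 higher and 31 lower in resistant cells; on protein-coding genes alone, a fit added after the data were seen, the split was 92 and 74 of 6330. Interferon genes had 3 of 12 called higher over all genes and 8 when adjusted over the list alone. Hypoxia and glycolysis genes had 3 of 12, and 5 adjusted over the list alone; autophagy and lysosome genes 1 of 24, and 4 adjusted over the list alone; iron genes 2 of 14 by either adjustment, the latter adjusted over the list alone. Mitochondrial respiration (17 tested), ferroptosis (17) and proliferation genes (7) had 0 called over all genes, and 0, 0 and 2 lower adjusted over the list alone. With DESeq2 size factors the split was 285 higher and 167 lower, and under total counts 194 and 6. The call rests on 1 residual degree of freedom: 0 genes were called with line as the only factor (416 at an unadjusted p under 0.05, by edgeR), 135 with DESeq2's Wald test and 345 with limma-voom. Leaving out 1 library left 1 library of 1 line. The only spread was then the drug difference in the other line, so those fits cannot check the call.

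Among iron genes, NCOA4 (Entrez 8031) itself did not differ detectably at this depth. Its counts were 33 in untreated and 28 in treated resistant cells and 31 and 19 in sensitive cells, giving a line fold of 1.45 (0.861 to 2.45) without drug and 1.05 (0.564 to 1.98) with it. FTH1 (Entrez 2495) had 627, 1361, 162 and 263 counts in the order of the depths above; it was 3.68-fold higher (3.22 to 4.21) in resistant cells under drug, and encorafenib went with a 3.20-fold increase (2.62 to 3.92) in sensitive and a 2.23-fold increase (2.03 to 2.46) in resistant cells. FTL (Entrez 2512), the ferritin light chain, differed less between lines, 1.31-fold (1.12 to 1.54) and 1.35-fold (1.20 to 1.52), and was 2.58-fold higher (2.22 to 2.99) with drug in sensitive and 2.65-fold higher (2.32 to 3.03) in resistant cells. Processed copies of the ferritin genes exist in the genome, and how reads shared with them were counted is not given in the sources used here. TFRC (Entrez 7037) had 68, 46, 9 and 10 counts, with a line fold of 3.27 (1.63 to 7.26) under drug and drug folds of 2.19 (0.801 to 6.10) in sensitive and 0.696 (0.468 to 1.03) in resistant cells. The mitochondrial iron importer SLC25A37 was lower with drug, at -2.06 (-2.42 to -1.72) in sensitive and -1.53 (-1.87 to -1.21) in resistant cells. SLC40A1, the iron exporter ferroportin, had 0, 4, 0 and 2 counts.

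As a list, 15 detected iron genes had medians of 0.07 (-0.24 to 0.40) without drug and 0.43 (0.09 to 0.83) with drug between lines, at percentiles 67.4 and 96.1. The second became -0.00814 over members with at least 50 counts, while scaling by total counts made it larger. Drug medians of the iron genes were 0.12 (-0.32 to 0.33) in sensitive cells, or -0.46 under scaling by total counts, and 0.28 (-0.12 to 0.50) in resistant cells, at percentiles 85.1 and 97.1. In the additive drug effect 2 of 14 were called higher and 1 lower over all genes, and 2 and 2 adjusted over the list alone. The 18 detected ferroptosis genes had line medians of -0.05 (-0.14 to 0.40) and 0.20 (-0.21 to 0.58) and drug medians of 0.17 (-0.34 to 0.45) and 0.14 (-0.29 to 0.36), at percentiles 39.5, 79.2, 83.0 and 80.25. Under total counts the ferroptosis line median with drug rose and the drug median in sensitive cells turned negative. The latter also turned negative over members with at least 50 counts. Members named by size were TXNRD1, thioredoxin reductase, at 1.48 (0.67 to 2.43) between lines under drug, and PTGS2, with 18 counts against 2 between untreated lines, at 3.28 (1.55 to 6.77). BRAF had 14, 14, 24 and 7 counts, with line folds of 0.795 (0.380 to 1.60) and 1.42 (0.537 to 4.16).

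**Figure D2:**
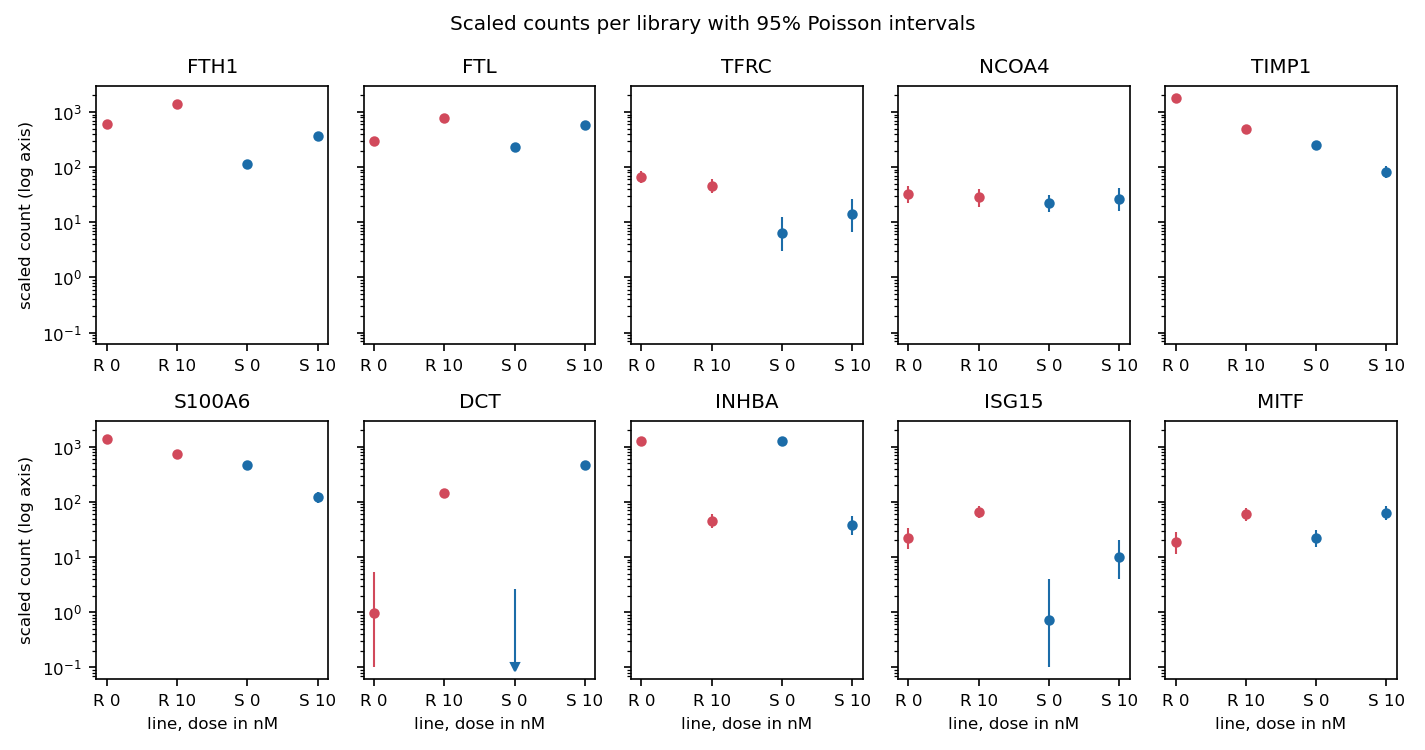
Counts of 10 genes scaled with TMM factors (y, log axis) in the 4 libraries (x; R resistant, S sensitive, 0 untreated, 10 with 10 nM encorafenib), with exact 95% Poisson intervals as bars and a triangle for a count of 0. FTH1 was higher in both resistant libraries, DCT was near 0 in both untreated libraries and INHBA was lower in both treated ones; the genes drawn were chosen after their values were seen.

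Encorafenib in sensitive cells went with lower transcript of MAPK outputs and proliferation genes, and with higher DCT and GPNMB. The melanocyte list as a whole had a median near 0 that changed with the count minimum and the scaling. INHBA, the inhibin beta A subunit of activin, had 27 counts against 1773, a log2 ratio of -5.04 (-5.66 to -4.51). SPRY4, a feedback inhibitor of MAPK signalling, had 0 counts against 112, at least 18.9-fold lower, and TOP2A, a topoisomerase of dividing cells, stood at -4.38 (-5.92 to -3.31). DCT had 332 counts against 0, at least 218-fold higher, and GPNMB stood at 5.69 (4.61 to 7.51). Of 8865 genes, 315 were higher and 222 lower, with 170 and 196 of them protein-coding and 93 of the higher ones snoRNA, and the treated library had the smallest protein-coding share. Under scaling by total counts the split turned to 139 higher and 575 lower.

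Other lower genes were the hyaluronan-degrading CEMIP, with 0 counts against 135 and at least 22.8-fold lower, IGFBP3, with 0 against 71 and at least 12.0-fold lower, SYTL5 at -5.32 (-7.76 to -3.91), the matrix link protein HAPLN1 at -4.85 (-6.39 to -3.79), ASPM and the EGFR ligand TGFA each at -4.68 (-7.12 to -3.25) and IER3 at -4.30 (-6.03 to -3.14). Higher genes were ANGPTL7, with 97 counts against 0 and at least 63.8-fold higher, the prohormone convertase PCSK2, with 78 against 0 and at least 51.3-fold higher, TCN1, a vitamin B12 carrier, at 6.54 (4.75 to 12.59) with 78 counts against 1, the semaphorin SEMA3C at 4.64 (4.18 to 5.20), ANK3 at 4.11 (3.63 to 4.67), MGP at 4.55 (3.51 to 6.19), TP53INP2 at 4.57 (3.45 to 6.41) and PCDH7 at 4.35 (3.37 to 5.84). MAPK outputs had a median of -1.86 (-2.86 to -1.60) at percentile 0, with 8 of 16 members lower beyond 2-fold and 0 higher, among them EGR1 at -4.41 (-6.85 to -2.98) and ETV4, with 0 counts against 65. Proliferation genes had a median of -3.38 (-4.08 to -2.66) at percentile 0, or -1.46 with members at 0 placed at their bound and -4.13 over members with at least 50 counts, and histones one of -1.80 (-2.21 to -1.35) at percentile 0.04. Interferon genes had a median of 1.499 (0.98 to 1.95) at percentile 100, with IFI6 at 2.77 (1.76 to 4.10) and IFIT3 at 2.75 (1.44 to 4.68). Beside this, CD68 had 17 counts against 6, at 2.36 (1.07 to 4.11). Of 7 detected melanocyte genes, DCT and the protease CAPN3, at 5.35 (3.49 to 11.41) with 34 counts against 1, were beyond 2-fold, and MITF, the melanocyte transcription factor, was 2.87-fold higher (1.77 to 4.68). The median of that list was 0.02 (-0.29 to 1.10) and its mean 2.20. Over members with at least 50 counts its median was well above 0, and under total counts it was below 0.

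With encorafenib in resistant cells, MAPK outputs were also lower, as was INHBA, and DCT was higher. INHBA stood at -4.81 (-5.29 to -4.40), and DCT, with 145 counts against 1, at 6.63 (4.72 to 12.53). The chemokine CXCL8 was lower at -4.56 (-7.07 to -3.17), and RELN, the secreted protein reelin, was higher at 1.92 (1.83 to 2.01), with 4528 counts against 1233. Of 8865 genes, 298 were higher and 141 lower, with 92 and 120 of them protein-coding and 97 of the higher ones tRNA. The microRNA table held 20808 counts in the untreated and 59045 in the treated resistant library, against 7041 and 4395 in sensitive cells.

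Lower genes also included IGFBP3 at -5.28 (-8.65 to -3.70), CEMIP at -5.23 (-8.61 to -3.65), HAPLN1 at -4.50 (-6.27 to -3.37), the kinase anchor AKAP12 at -3.60 (-4.09 to -3.17), CDCP1 at -5.07 (-10.96 to -3.09) with 1 count against 51, FERMT1 at -3.63 (-4.96 to -2.68), KIAA0040 at -4.30 (-7.69 to -2.67) and the phosphate transporter SLC20A1 at -3.24 (-3.93 to -2.67). Higher genes also included PCSK2, with 78 counts against 0 and at least 26.7-fold higher, ANGPTL7, with 52 against 0 and at least 17.8-fold higher, ANK3 at 3.96 (3.44 to 4.58), NIBAN1 at 3.33 (2.56 to 4.33), SEMA3C at 2.60 (2.18 to 3.08) and THBS1 at 2.42 (1.85 to 3.08). TUBA1A at 2.97 (2.25 to 3.86) and PCDHGC3 at 2.93 (1.99 to 4.19) share sequence with related genes and are uncertain. MAPK outputs had a median of -1.41 (-1.86 to -0.99) at percentile 0, with DUSP6 at -2.34 (-3.06 to -1.73) and CCND1 at -1.99 (-2.50 to -1.53). Proliferation genes had a median of -1.42 (-1.80 to -0.48) at percentile 0, or -2.41 over members with at least 50 counts. Of their 20 intervals, 3 lay below 0 and 17 included 0. Cell-matrix genes had a median of -0.72 (-1.06 to -0.46) at percentile 0.01, with TIMP1 at -1.88 (-2.03 to -1.74) and ITGB3 at -1.70 (-2.15 to -1.29). Interferon genes had a median of 1.56 (1.18 to 1.97) at percentile 100, or 0.92 over members with at least 50 counts, with IFIT2 at 3.12 (1.92 to 4.93), beside CD68 with 35 counts against 22, at 0.70 (-0.10 to 1.55), and p53 targets one of 0.57 (0.20 to 0.78) at percentile 99.4. MITF was 3.19-fold higher (1.88 to 5.67). The melanocyte list had a median of -0.09 (-0.35 to 1.37) and a mean of 1.43, and its median over members with at least 50 counts was well above 0.

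The 2 drug comparisons share no library, and 112 genes were higher and 73 lower in both, where independent lists would share 10.6 and 3.53; 10 genes went opposite ways. Of the shared genes, 55 and 68 were protein-coding. The expected numbers again take all entries as independent, which entries with identical counts are not. Across 509 protein-coding genes the drug ratios correlated with Pearson's r of 0.674 and Spearman's rho of 0.597. The additive fit, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, called 407 of 7092 genes for the drug, 241 higher and 166 lower; on protein-coding genes alone it called 610 of 6330, with 290 higher and 320 lower. MAPK outputs had 8 of 15 called lower over all genes and 11 adjusted over the list alone, proliferation genes 3 of 7 and 5 adjusted over the list alone, and melanocyte genes 3 of 6 higher, also 3 adjusted over the list alone. Interferon genes had 4 of 12 called higher, and 5 adjusted over the list alone. Total counts gave 82 higher and 151 lower, DESeq2 size factors 837 genes and no filter 752 of 18563. DESeq2's Wald test gave 187 genes, limma-voom 612 and the drug as the only factor 8. Leaving out 1 library left 1 treated or 1 untreated library. The only spread was then the difference between the lines in the other group, so those fits cannot check the call.

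The difference between the drug responses has no test in this design. Of 1799 protein-coding genes with at least 50 counts in a library, 16 had a response higher and 20 a response lower in sensitive cells by over 2-fold at the counting bound; total counts turned these to 4 and 109. GPNMB differed by 4.45 (3.09 to 5.82) in log2, ITGA2 by 3.51 (2.84 to 4.18) and the transcription factor JUN by 2.84 (1.61 to 4.08), all higher in sensitive cells. DPYSL2 differed by -4.83 (-7.00 to -2.66), the serine synthesis enzyme PHGDH by -3.79 (-5.56 to -2.02), SLC7A5 by -3.22 (-4.54 to -1.89) and PYGB by -2.74 (-3.80 to -1.68). ITGA2 stood at 2.31 (1.81 to 2.85) with drug in sensitive cells and had 55 counts against 131 in resistant cells.

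**Figure D3:**
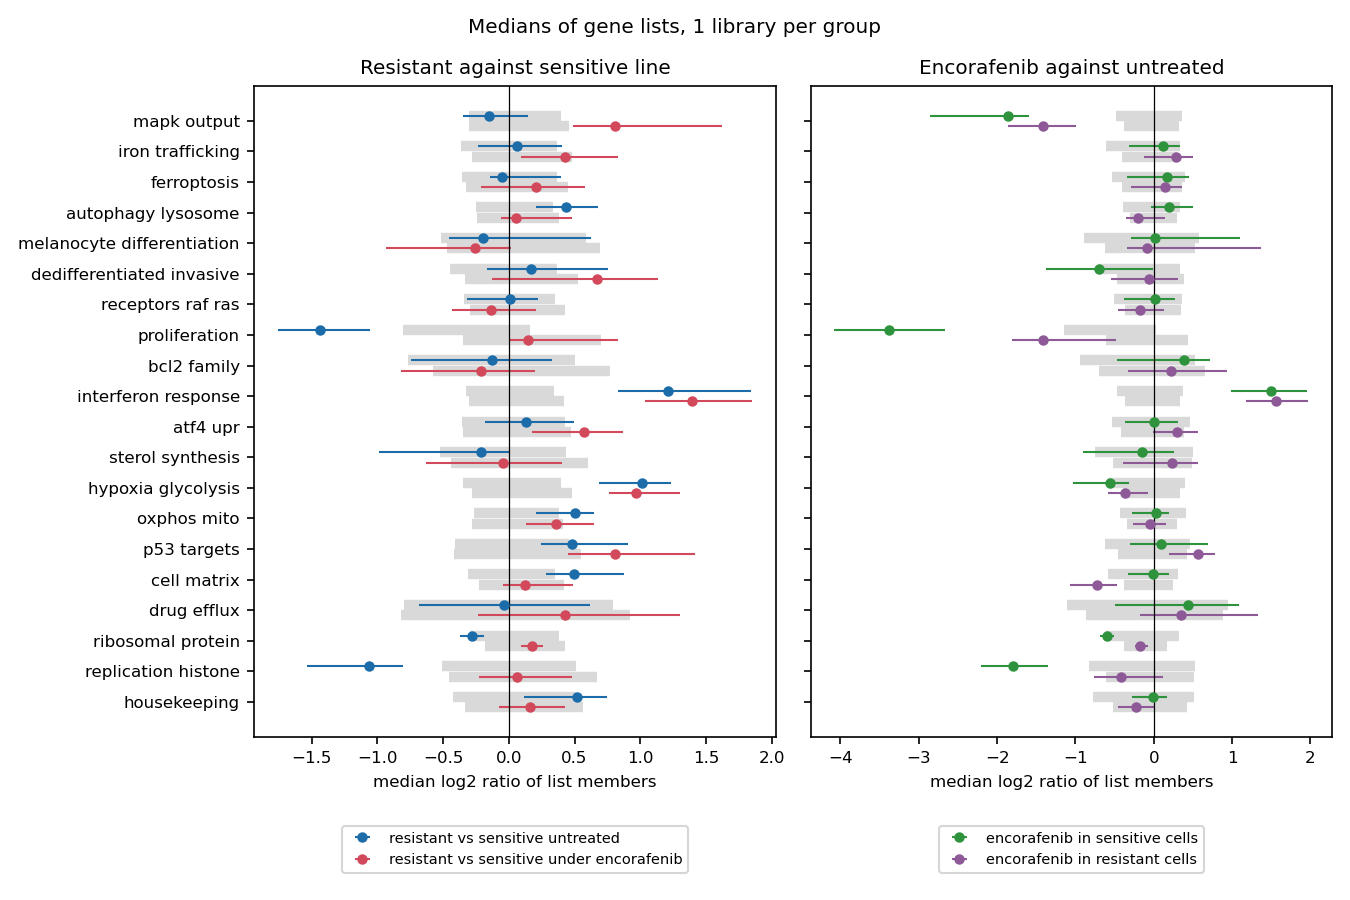
Median log2 ratio of each gene list (x) by list (y), for the pair of line comparisons on the left and the pair of drug comparisons on the right, with 95% intervals from Poisson redraws as thin bars and the 95% range of 10000 matched random lists as grey bars. Interferon genes lie between 1.21 and 1.56 in all 4 comparisons, and proliferation genes lie at -3.38 and -1.42 in the drug comparisons.

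The let-7 family of microRNA, which represses growth genes, was higher in resistant cells. Without drug let-7c-5p stood at 4.00 (3.43 to 4.69), let-7b-5p at 3.43 (3.11 to 3.78) and let-7a-5p at 3.28 (3.10 to 3.48), and under drug at 4.15 (3.24 to 5.30), 2.96 (2.54 to 3.43) and 3.20 (2.92 to 3.51). Its 9 members had medians of 2.73 (2.43 to 3.40), or 2.56 with members at 0 placed at their bound, and 3.20 (2.76 to 3.90), at percentiles 99.7 and 99.3. Members of the family share sequence, and how reads matching several of them were counted is not given in the sources used here. Single members are therefore uncertain, and let-7a-5p alone held 3850 of the list's 6708 counts in untreated resistant cells. Of 190 microRNA, 26 were higher and 9 lower without drug and 36 and 22 under drug, with 22 and 5 shared, where independent lists would share 4.93 and 1.04. Both resistant libraries also held more microRNA reads in all. Under scaling by total counts the splits were 10 higher and 32 lower without drug and 21 and 37 under drug, and the let-7 medians 1.92 and 2.40.

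Also higher in both were miR-31-5p, at 3.48 (2.72 to 4.45) and 3.40 (2.49 to 4.56), and miR-1246, with 53 counts against 1 at 4.54 (2.45 to 10.32) and 246 against 0, at least 10.4-fold higher. Under drug miR-221-3p stood at 4.80 (3.30 to 7.14), let-7d-5p at 5.44 (3.10 to 10.89) and the hypoxia-induced miR-210-3p, with 242 counts against 0, at least 10.2-fold higher. Lower in both were miR-296-5p at -2.12 (-2.49 to -1.78) and -2.11 (-2.53 to -1.70) and miR-6516-3p at -1.33 (-1.84 to -0.84) and -3.40 (-3.89 to -2.95). So were miR-331-3p at -3.12 (-4.08 to -2.37) and -1.22 (-1.70 to -0.72), miR-3180-5p at -1.26 (-1.66 to -0.87) and -1.71 (-2.09 to -1.34), and let-7d-3p at -0.92 (-1.35 to -0.50) and -1.08 (-1.49 to -0.66). Among these miR-296-5p alone passed 2-fold at the bound in both comparisons, so the rest are not among the 5 shared ones counted above. Under drug miR-328-3p stood at -2.20 (-2.42 to -1.99), miR-1908-5p at -2.12 (-2.72 to -1.53) and miR-92b-3p at -1.71 (-1.98 to -1.43). The invasion and resistance list had medians of 2.35 (1.80 to 2.82) and 3.72 (3.12 to 4.70), or 1.23 and 2.96 with members at 0 placed at their bound, at percentiles 98.2 and 99.1. The miR-17-92 list had medians of 1.95 (1.18 to 2.48) and 2.17 (1.46 to 3.57), at percentiles 92.3 and 83.7. The melanocyte microRNA list, with 3 members, had medians of 2.07 and 3.86, or 2.02 and 1.19 with members at 0 at their bound, at percentiles 90.4 and 84.3. The miR-200 and DLK1-DIO3 lists had under 3 detected members. Across 53 microRNA the line ratios correlated with r of 0.860. The additive fit, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, called 70 of 121 between lines, 40 higher and 30 lower, against 26 and 39 under total counts and 39 in all with DESeq2's Wald test. It called 8 of 9 let-7 members, which may share reads, higher over all microRNA and 8 adjusted over the list alone.

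Between treated and untreated libraries, 5 microRNA were higher and 2 lower beyond 2-fold in resistant cells; at this depth 50% of simulated 4-fold changes were recovered there and 20% in sensitive cells. In resistant cells the p53-induced miR-34a-5p was higher at 2.45 (1.57 to 3.57), miR-140-3p at 1.86 (1.48 to 2.28), miR-103a-3p at 2.12 (1.30 to 3.12), miR-29a-3p at 1.57 (1.11 to 2.09) and miR-181b-5p at 2.18 (1.04 to 3.70), and miR-574-5p at -1.499 (-1.86 to -1.15) and miR-6516-3p at -1.52 (-2.06 to -1.003) were lower. In sensitive cells 2 were higher and 1 lower, the latter miR-125b-5p at -1.37 (-1.64 to -1.12). Total counts gave 11 higher and 0 lower in resistant and 3 and 0 in sensitive cells, and DESeq2 size factors 9 and 1 in resistant cells. Members of let-7 had drug medians of -0.76 (-1.01 to -0.08) and -0.62 (-0.79 to -0.46), at percentiles 8.55 and 1.68. With 5 expression bins the second percentile was 2.81, within the 95% range, and the mean in resistant cells was -0.26. Across 53 microRNA the drug ratios correlated with r of 0.168.

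Receptor, RAF and RAS genes had a median of 0.01 (-0.32 to 0.22) between untreated lines over 20 members, with IGF1R at -1.39 (-2.08 to -0.77) with drug in sensitive and -1.08 (-1.84 to -0.39) in resistant cells. BCL2 family genes had a median of -0.13 (-0.75 to 0.33) over 9 members, with MCL1 at -1.54 (-2.13 to -1.01) and -2.23 (-2.81 to -1.72) with drug, and sterol synthesis genes one of -0.21 (-0.99 to 0.00) over 13 members. Drug efflux transporters had a median of -0.04 (-0.69 to 0.62) over 4 members. Dedifferentiation and invasion genes had a median of 0.67 (-0.13 to 1.14) under drug between lines, at percentile 99.3, while their summed counts went the other way, at -0.41 (-0.61 to -0.21), and TNC stood at 1.22 (0.28 to 2.31). With drug in sensitive cells their median was -0.70 (-1.38 to -0.01), or -0.10 with members at 0 placed at their bound, at percentile 2.90, and their summed ratio 0.62 (0.43 to 0.81). Ribosomal protein genes had a median of -0.60 (-0.68 to -0.51) with drug in sensitive cells at percentile 3.63. Of 8 markers each, 0 fibroblast and 0 endothelial markers were detected, 2 keratinocyte markers (KRT10 and DSP), 1 epithelial marker (KRT18) and 2 immune markers (LYZ and CD68). LYZ had 13, 2, 1 and 0 counts and CD68 22, 35, 6 and 17. The 9 mitochondrially encoded genes matched 0 entries of the table.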

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

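The tests for immune cells and for NRF2 targets were chosen only after the result was seen; the other tests named here were set out before theirs.

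In all, 10 entries responded to encorafenib in opposite directions in the lines, each beyond 2-fold at its bound; the difference itself was not tested. The log2 response in sensitive minus resistant cells, with counts of 0 set to the floor of 3, was -7.41 for each of the glycine tRNA genes TRG-GCC2-1, TRG-GCC2-2, TRG-GCC2-3 and TRG-GCC2-4, whose counts of 0, 173, 17 and 0 were identical. It was -6.73 for the spliceosomal RNVU1-18, -6.82 for RNU6-7 and -5.18 for RNU6-1, both U6 RNA, and 2.55 for the rRNA precursor RNA45SN2. CT45A3, a cancer-testis gene with near-identical copies, stood at -3.60, and the pseudogene GBAP1 at 5.94, with 24, 0, 0 and 12 counts. How reads shared between copies were assigned is not given in the sources used here, so these counts are uncertain.

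Resistant libraries held more microRNA and tRNA. Depth was not tested by microRNA-table reads per gene-table read, 4.32-fold higher (4.20 to 4.44) without and 16.7-fold higher with drug. These shares are the pattern itself. Gene-table totals were larger in sensitive cells, 33664470 without and 25539835 with drug, against 23029101 and 20507667 in resistant cells. These totals argue against lower depth of the sensitive libraries. A difference in the recovery of short RNA is a candidate explanation: over 250 snoRNA genes, shorter ones had the higher line ratios, with Spearman's rho of -0.49 without and -0.62 with drug. Y RNA was 0.859-fold without drug and 2.80-fold with it. A larger pool of small RNA in resistant cells stays open and untested, as does the library preparation, since each group is 1 library.

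Interferon-response genes were higher in resistant cells with and without drug. GC content and transcript length are argued against as the whole cause: with their trend removed the list medians were 1.27 and 1.35, both at percentile 100. Immune cells and a line difference cannot be told apart from these counts: the 8 immune markers summed to 35 counts without and 38 with drug in resistant cells, against 8 and 17 in sensitive cells, but nearly all came from LYZ (13 and 2) and CD68 (22 and 35). The other 6 summed to 0 and 1; a first form of this test used those 6 alone, picked once the counts were known, and was replaced. An interferon state of the resistant line stays open as a hypothesis, as do differences between cultures that 1 library per group leaves untested.

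FTH1 and TFRC were both higher in resistant cells. GC content and length are argued against, with 1.73 in log2 the smallest of the corrected ratios. A gain of the neighbourhood shared by both comparisons is also argued against. The 40 neighbours summed to 0.20 (0.13 to 0.28) without and -0.56 (-0.64 to -0.49) with drug around FTH1. Around TFRC they summed to 0.21 (0.03 to 0.40) without and -0.11 (-0.33 to 0.12) with drug. Abundant genes decide these sums, and only 19 and 16 of the 40 neighbours reached 10 counts. The medians of those were -0.17 and 0.03 around FTH1 and 0.32 and -0.07 around TFRC. Around TFRC without drug the sum and the median both lay above 0. For TFRC the argument thus rests on the comparison with drug alone. A list of NRF2 targets without ferritin genes had medians of 0.61 and 0.66 over 12 detected members, at percentiles 99.51 and 99.11, so higher NRF2 output may go with FTH1. Against this, housekeeping genes stood nearly as high without drug, at 0.52 and percentile 97.8, and some targets were not higher: GCLC at -0.24 and -0.08, SLC7A11 at -0.26 without and SRXN1 at -0.93 with drug. That list does not hold TFRC, whose increase stays open.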

How the results depend on the processing

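Alternatives for the difference of responses, entries with identical counts taken once, removal of genes overlapping small RNA and the additive fit on protein-coding genes were chosen after the data were seen. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers; the additive fit takes line and drug as blocks of each other instead. Of the values that answer a comparison, 232 kept their direction and size under an alternative, 84 moved, 1 reversed and 1 became weaker; of the others 384 kept theirs, 51 moved, 4 became stronger and 1 weaker. The smallest microRNA library had 4395 counts, and for the drug in sensitive cells 20% of simulated 4-fold and 50% of 8-fold microRNA changes were recovered, against 34% and 84% for genes.

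Total counts moved ratios by the shift of the median gene given above, and of the median microRNA by -0.67 and -0.77 between lines and 0.07 and 0.23 with drug in sensitive and resistant cells. Medians between lines under drug became 1.24 for iron, 0.98 for ferroptosis, 0.55 for melanocyte, 0.87 for proliferation and 2.18 for interferon genes. With drug in sensitive cells they became -0.46 for iron, -0.39 for ferroptosis, -0.56 for melanocyte and 0.95 for interferon genes. Counts became 716 higher and 31 lower between lines under drug and 139 and 575 with drug in sensitive cells. For let-7, medians became 1.92, 2.40 and, with drug in resistant cells, -0.39. MicroRNA counts became 10 and 32 between untreated lines, 21 and 37 under drug, 0 lower with drug in sensitive cells, and 11 and 0 in resistant cells. The additive drug effect gave 233 genes, and the difference of responses 4 higher and 109 lower in sensitive cells.

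Over list members with at least 50 counts, the iron median between lines under drug reversed to -0.00814, close to 0, and the interferon median became 1.01. Drug medians became -0.40 for ferroptosis, 1.499 for melanocyte and -4.13 for proliferation genes in sensitive cells, and 1.65 for melanocyte, -2.41 for proliferation and 0.92 for interferon genes in resistant cells, each over fewer members. Means over members gave 2.20 and 1.43 for melanocyte genes in sensitive and resistant cells and -0.26 for let-7 in resistant cells. A prior count of 3 gave -1.87 for proliferation genes in sensitive cells, 2.37 for let-7 between untreated lines, and 9 and 13 genes for the difference of responses. With 5 bins the let-7 percentile in resistant cells was 2.81, within the 95% range.

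With at least 50 counts, fewer genes were tested: 52 were lower between untreated lines, 155 higher under drug, 122 lower with drug in sensitive and 84 lower in resistant cells; of microRNA, 10 were higher between untreated lines, 16 under drug, and 1 higher and 0 lower with drug in sensitive cells. On protein-coding genes only, 81 were higher and 61 lower between untreated lines, 46 and 43 under drug, and 186 and 93 higher with drug in sensitive and resistant cells, again of fewer genes. At the point estimate, 159 were lower between untreated lines. Thinned libraries gave 17 and 4 microRNA between untreated lines, 8 lower under drug, and 1 and 1 with drug in resistant cells, at lower depth. No filter gave 0 microRNA lower with drug in sensitive and 16 and 0 in resistant cells, and DESeq2 size factors 9 and 1 in resistant cells; the cause was not tested.

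For the additive fit, the line effect gave 371 genes with no filter, 452 with DESeq2 size factors, 345 with limma-voom and 0 with 1 factor (416 at an unadjusted p under 0.05, by edgeR). The drug effect gave 752, 837, 612 and 8, and 187 with DESeq2's Wald test, which gave 39 microRNA between lines. On protein-coding genes alone the line effect split into 92 higher and 74 lower, against 142 and 31 over all genes, and the drug effect into 290 and 320, against 241 and 166. The cause was not tested. Leaving out 1 library in fits with 1 factor gave 12 to 261 genes for the line (12 without treated resistant, 45 without untreated resistant, 226 without treated sensitive and 261 without untreated sensitive cells), 23 to 130 for the drug (23 without untreated sensitive and 130 without treated resistant cells) and 39 to 59 microRNA (39 without treated resistant and 46 without treated sensitive cells).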

Other observations

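The test of gene order below was set out before its result was seen.

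Genes named in this part were chosen after their values were seen. With drug, the receptor tyrosine kinase AXL stood at -1.65 (-2.88 to -0.66) in sensitive and -1.02 (-1.93 to -0.19) in resistant cells. The transporter ABCC2 stood at 1.60 (0.43 to 2.96) and 1.80 (0.80 to 3.03). These intervals exclude 0 but do not pass 2-fold at the bound.

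In the BCL2 family, BCL2L11, the activator of apoptosis known as BIM, had 10 counts against 2 with drug in sensitive cells, 2.94 (1.07 to 6.53), and 2 against 1 in resistant cells. BMF had 11 counts against 1 in sensitive cells, 3.75 (1.66 to 9.87), and 6 against 1 in resistant cells, 2.15 (-0.42 to 8.15). These ratios rest on few counts, and the difference between lines was not tested. Dedifferentiation genes were split: with drug in sensitive and resistant cells THBS1 stood at 2.503 (2.13 to 2.91) and 2.42 (1.85 to 3.08), and TNC at -2.21 (-3.24 to -1.38) and 0.08 (-0.60 to 0.75).

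Neighbouring genes shared part of the difference between the lines. Over 250 windows of 30 neighbouring genes, the window medians of the pair of line comparisons correlated with r of 0.339, and 0 of 100 shuffles of gene order gave a value as high, the highest being 0.295 and their median 0.171. The shuffles test only the order of genes. The ratios were not corrected for GC content or transcript length, and entries with identical counts were kept. The fitted trend with GC content and length had an SD over genes of 0.106 without and 0.158 with drug. Which windows differ, and whether GC content, length, shared reads or DNA copy number lies behind it, was not tested. As description only, the largest shift shared by both comparisons was in the window from BET1L to NAP1L4 on chromosome 11. Its medians were 0.52 without and 0.60 with drug. Chromosome 11 also had the highest chromosome medians, 0.17 without and 0.20 with drug.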
